A study of Mus musculus with 60 samples.

How the data were processed

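RNA from mouse duodenum organoids was prepared by the submitters with a QuantSeq 3′ mRNA-seq kit (forward) and sequenced on an Illumina machine. The labels place 60 samples in 20 groups of 3 by genotype, treatment and time, and samples were grouped by these labels alone. The processing notes of the labels name Salmon, without a version, as the quantification tool. The genome build, annotation, normalization, filters and statistical test behind the values are not given in the sources used here.

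The file analysed was the authors' deposited table of 13 comparisons. Per the file headers it holds, for each gene and comparison, a log2 fold change of the first condition named against the second, the linear fold change as a ratio, a p-value, an FDR p-value and a Bonferroni p-value. Missing values are written as text in this table, for which reason its columns were recorded under a general unit. It was checked that the deposited fold change equals 2 to the power of the deposited log2 fold change, that the deposited FDR p-value equals a Benjamini-Hochberg adjustment of the p-values, and that the Bonferroni p-value is the p-value times the number of genes. Values were present for 24905 genes in all comparisons, and for 24907 in 2 of them. Values per sample were not analysed here, so the depth of each sample is unknown, and no replicate could be compared, left out or used as a block. The 3 comparisons of genotypes under DMSO that were planned were not analysed here, because the table holds none of them.

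A standard error was derived for each gene and comparison as the size of the log2 fold change divided by the normal quantile of its two-sided p-value. This reading assumes a Wald-type test, which is not stated. Intervals are 95% normal intervals from this standard error. The difference between a genotype's response and that of its wild type was the difference of the deposited log2 fold changes, with standard errors combined as independent, a two-sided normal p-value and a Benjamini-Hochberg adjustment over 24905 genes. A gene was called at an adjusted p under 0.05. If all p-values were uniform, 1245 genes would have p under 0.05; every comparison had fewer, and the scaled median absolute deviation of the z scores in well measured genes ran from 0.654 to 0.976. Well measured means a median standard error of at most 0.5 over the 13 comparisons (9526 genes). This limit, and the limit of 1 used for gene lists (11826 genes), were chosen after the table was seen.

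Gene lists were fixed, with the treatment comparisons, their differences and the naming rule, before the data were examined; the 3 comparisons between times of DMSO were added after the table was seen. There were 34: E2F and G1/S genes, DNA replication machinery, G2/M and mitosis genes, cyclins with CDKs and CDK inhibitors, p53 targets, markers of stem, Paneth, goblet, enteroendocrine, tuft and enterocyte cells, fetal-like and regeneration genes, Wnt targets, Notch pathway, interferon and antigen presentation, NF-kB and inflammatory genes, cholesterol biosynthesis, fatty acid oxidation and PPAR targets, unfolded protein and integrated stress response, NRF2 and glutathione, AhR, PXR and CAR xenobiotic genes, estrogen-responsive, heat shock, immediate early, hypoxia and glycolysis, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, mitochondrially encoded genes, apoptosis, CDK5-associated genes, and markers of fibroblasts, immune cells, endothelial and neural cells, and gastric and pancreatic cells. Each was tested with cameraPR of limma on the z scores of genes with a median standard error of at most 1, with a preset correlation of 0.01, two-sided, adjusted over the 30 lists with at least 5 such members. The estimated correlation of a list was taken from the z scores of its members in the comparisons that did not enter the test. It is an approximation that counts real joint movement as correlation, and some comparisons share libraries. A further 3 lists, of spermatid, meiotic germ cell, and Sertoli and Leydig cell transcripts, were written after the calls in WT-cKO organoids at 24 h were seen and tested over all genes with a value. In the WT-cKO comparison at 24 h and its difference from CDK2-cKO, the spermatid test was run on the 55 genes neither called nor looked at before.

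The naming rule took Cdk2 and Cdk5 in every comparison, the 10 called genes with the largest rise and the 10 with the largest fall per treatment comparison (5 and 5 for wild types and differences), and up to 4 members with the smallest adjusted p from each list that passed. Its demands on non-overlapping replicate values and on a minimum mean level could not be applied to a table of comparisons. Predicted genes without a symbol were passed over and counted. Positions are from GENCODE M21 on GRCm38 by symbol, which held 95.9% of the 24905 symbols.

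Agreement between CDK2 degradation and CDK2 knockout was measured by Pearson and Spearman correlation across genes. Alternatives tried were a Bonferroni adjustment, a fold change of at least 1.5, the well measured genes alone, z scores of the well measured genes centred and rescaled by their own median and spread, and for lists the estimated correlation, ranks, all genes, and well measured genes. The calling step was tested on simulated data drawn from the derived standard errors with 100 well measured genes changed 2-fold and 100 changed 4-fold. In CDK2-dTAG at 24 h it recovered 59% of the former and 98% of the latter, with 14 false calls. For differences between genotypes it recovered 22% to 38% and 78% to 92%. The Benjamini-Hochberg cutoff loosens as more genes change. These shares therefore do not give the recovery where few genes change, nor that outside the well measured genes. A simulated shift of 26 genes by 1 unit of z was found in 94 of 100 draws. All genes were drawn independently there, so the draws do not test a list whose members move together. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.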

Results

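Gene expression was measured by 3′ mRNA sequencing in organoids grown from mouse duodenum, the first part of the small intestine. The study asked what loss of the cell-cycle kinase CDK2, or of CDK5, a cyclin-dependent kinase best known from neurons, does in adult tissue. In the degron arm, WT-dTAG, CDK2-dTAG and CDK5-dTAG organoids received DMSO or 250 nM dTAG-13 for 6 or 24 h. A dTAG fusion lets the small molecule dTAG-13 bring the tagged protein to a ubiquitin ligase, after which the protein is degraded. In the conditional knockout arm, WT-cKO and CDK2-cKO organoids received DMSO or 1 uM 4-OHT (4-hydroxytamoxifen, commonly used to switch on a tamoxifen-dependent Cre recombinase) for 24 or 48 h. The labels gave 3 replicates for each of 20 groups, 60 samples in all, with 36 in 12 degron groups and 24 in 8 knockout groups. Nothing in the labels says whether replicates were separate cultures or animals, so the p-values measure only the spread between these samples. The values used here are the authors' own comparisons, 13 in number, each with a log2 fold change and p-value per gene; the depth of each sample is therefore unknown. Of the genes listed, 24905 had values in every comparison. The median standard error implied by a gene's fold change and p-value ran from 1.05 on the log2 scale in CDK2-cKO organoids at 48 h to 1.37 in CDK2-dTAG organoids at 6 h. In 9526 genes the median over the 13 comparisons was at most 0.5.

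The targets themselves were read first, to ask whether either treatment lowered its own transcript. Cdk2 (GRCm38 chromosome 10, 128697939 to 128705031, minus strand) was lowest in CDK2-cKO organoids after 48 h of 4-OHT, at a log2 fold change of -0.64 with FDR p = 0.996 in the authors' deposited table. The 95% interval implied by its p-value was -1.08 to -0.20. In WT-cKO organoids at 48 h the authors' deposited table gave Cdk2 -0.53, and the difference between the genotypes was -0.11 (95% interval -0.72 to 0.49, adjusted p = 1.00). At 24 h Cdk2 stood at -0.35 in CDK2-cKO and 0.26 in WT-cKO organoids in the authors' deposited table. That difference was -0.61 (95% interval -1.20 to -0.02, adjusted p = 0.995), so it did not pass the test over all genes. Degradation acts on protein, so a transcript level does not report on it. In CDK2-dTAG organoids the authors' deposited table gave Cdk2 0.06 at 6 h and 0.16 at 24 h. Cdk5 (GRCm38 chromosome 5, 24418241 to 24423530, minus strand) was listed at -0.39 at 6 h and -0.30 at 24 h in CDK5-dTAG organoids in the authors' deposited table, with intervals of -1.19 to 0.40 and -1.08 to 0.49. A 3′ tag outside a deleted exon would also leave the transcript count in place. Neither transcript passed FDR p under 0.05 in any of the 10 treatment comparisons. Protein was not among the values used here, so loss of either kinase was not shown. Degradation and knockout below name the genotype and its treatment.

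**Figure D1:**
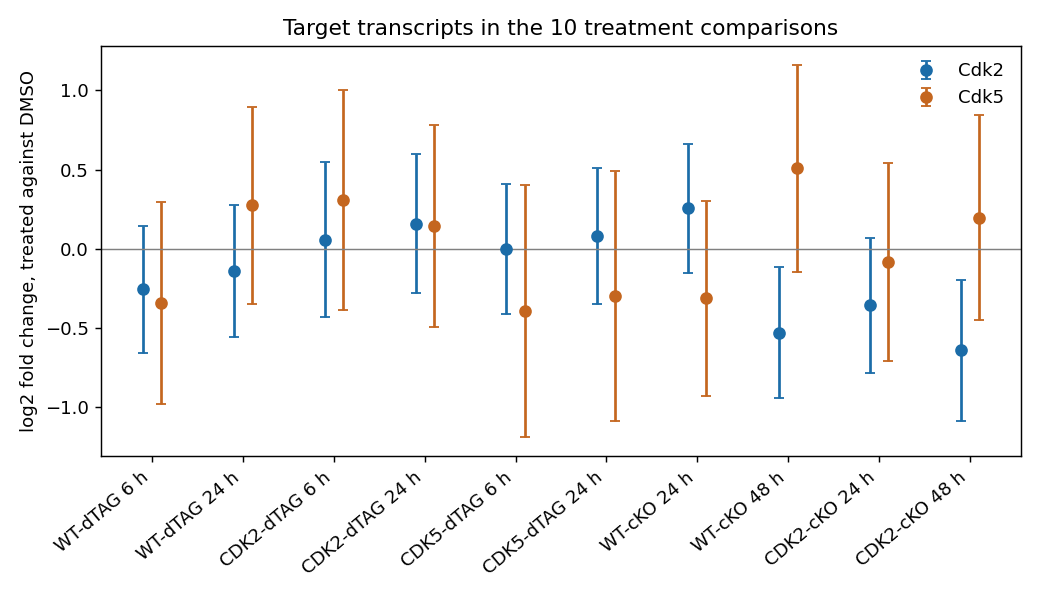
Log2 fold change of Cdk2 and Cdk5, treated against DMSO, in the 10 treatment comparisons; points are the values of the authors' deposited table and bars the 95% intervals implied by their p-values. Cdk2 was lowest in CDK2-cKO organoids at 48 h (-0.64), next to -0.53 in WT-cKO organoids at the same time.

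In WT-dTAG organoids, which show what dTAG-13 does without a tagged kinase, no single gene passed, and the lists fixed in advance that passed had medians of at most 0.25. At 6 h the mitochondrially encoded genes rose as a group, with a median log2 fold change of 0.19 and 15 of 15 positive (adjusted p = 0.00122); adjusted p = 0.986 with an estimated correlation. Among them the authors' deposited table gave mt-Nd1 0.26, mt-Cytb 0.22, mt-Atp6 0.25 and mt-Nd4 0.23. At 24 h the cytosolic ribosomal proteins rose by a median of 0.12, with 44 of 44 positive (adjusted p = 0.00350); adjusted p = 0.980 with an estimated correlation. Genes of the fetal-like and regeneration programme, such as Il1rn (1.04), Ly6d (1.09) and Anxa1 (0.78) in the authors' deposited table, rose by a median of 0.25 with 14 of 17 positive (adjusted p = 0.0442). For them adjusted p = 0.980 with an estimated correlation, and adjusted p = 0.222 on the genes with a median standard error of at most 0.5. No member of any of these lists passed FDR p under 0.05, nor when adjusted over the list alone. Over all genes the authors' deposited table held 0 genes with FDR p under 0.05 at 6 h and 0 at 24 h, against 199 and 269 at unadjusted p under 0.05. A uniform spread of p-values would give 1245 such genes, so these p-values run high.

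CDK2 degradation asks what acute loss of the kinase changes in the same organoids. After 24 h of dTAG-13, intestinal stem cell markers were higher in CDK2-dTAG organoids: 25 of 26 were positive, with a median log2 fold change of 0.29 (adjusted p = 3.49e-07); adjusted p = 0.435 with an estimated correlation. The authors' deposited table gave 0.92 for the RNA-binding protein Msi1, 0.47 for the transcription factor Sox9, 0.37 for the transporter Slc12a2 and 0.35 for the water channel Aqp4. Wnt target genes, 10 of which are also on the stem cell list, rose by a median of 0.32 with 16 of 17 positive (adjusted p = 0.00139); adjusted p = 0.486 with an estimated correlation. Within this group the authors' deposited table gave Sp5 1.96, Ccnd1 0.33, Ascl2 0.41 and Axin2 0.37.

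Other groups were lower after 24 h of CDK2 degradation. Cytosolic ribosomal proteins fell by a median of -0.13, all 44 negative (adjusted p = 2.09e-05); adjusted p = 0.808 with an estimated correlation. Rpl35 stood at -0.33 and Rpl18 at -0.19 in the authors' deposited table. Interferon and antigen presentation genes fell by a median of -0.20 with 17 of 19 negative (adjusted p = 0.0159); adjusted p = 0.297 with an estimated correlation. The authors' deposited table gave -1.21 for the interferon regulator Irf7 and -1.77 for Xaf1; on the genes with a median standard error of at most 0.5 this list had adjusted p = 0.419. The cell cycle lists did not pass: the median was 0.09 for E2F and G1/S genes (adjusted p = 0.416), 0.08 for the DNA replication machinery (adjusted p = 0.509), 0.00 for G2/M and mitosis genes (adjusted p = 0.654) and 0.11 for cyclins, CDKs and CDK inhibitors (adjusted p = 0.218). The p53 target genes had a median of 0.01 (adjusted p = 0.654). At 6 h none of the 30 lists passed, and the p53 targets stood at a median of -0.14 (adjusted p = 0.333). Standard errors were larger in this 6 h comparison, with a median ratio of 1.12 to WT-dTAG at 6 h over 325 best measured genes. Of the 3 labelled libraries of its DMSO group, 1 may not have entered the fit. Simulated 2-fold changes were recovered in 46% of genes there, against 59% at 24 h.

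The 24 h DMSO group of CDK2-dTAG organoids, the reference for these shifts, was also compared with 6 h of DMSO, and 3 of the lists moved the other way there. Stem cell markers had a median of -0.19 (adjusted p = 0.0364; adjusted p = 0.744 with an estimated correlation), ribosomal proteins 0.11 (adjusted p = 0.0409; adjusted p = 0.857 with an estimated correlation) and interferon and antigen presentation genes 0.36 (adjusted p = 0.0441; adjusted p = 0.441 with an estimated correlation). For these lists the comparison with DMSO at 24 h does not separate an effect of CDK2 degradation from the state of that DMSO group.

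No single gene carried these shifts. In CDK2-dTAG organoids the authors' deposited table held 0 genes with FDR p under 0.05 at 6 h and 0 at 24 h, with 225 and 267 at unadjusted p under 0.05. The difference from WT-dTAG, computed from both deposited fold changes, gave 0 genes at 6 h (281 at unadjusted p under 0.05) and 0 at 24 h (328), with a smallest adjusted p of 0.334 at 24 h. As groups, the stem cell markers differed from wild type by a median of 0.32 at 24 h, with 22 of 26 positive (adjusted p = 1.71e-04; adjusted p = 0.918 with an estimated correlation). The ribosomal proteins differed by -0.26, all 44 negative (adjusted p = 9.31e-08; adjusted p = 0.918 with an estimated correlation), where wild type alone was higher and CDK2-dTAG alone lower. For Wnt targets the difference was 0.32 and did not pass (adjusted p = 0.103). Spermatid transcripts, a list written later, differed by 0.93 at 24 h with 45 of 66 positive (adjusted p = 0.0124 with the preset and adjusted p = 0.831 with an estimated correlation). Adjusted over the list alone, 0 stem cell markers and 0 Wnt targets passed in CDK2-dTAG organoids at 24 h.

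**Figure D2:**
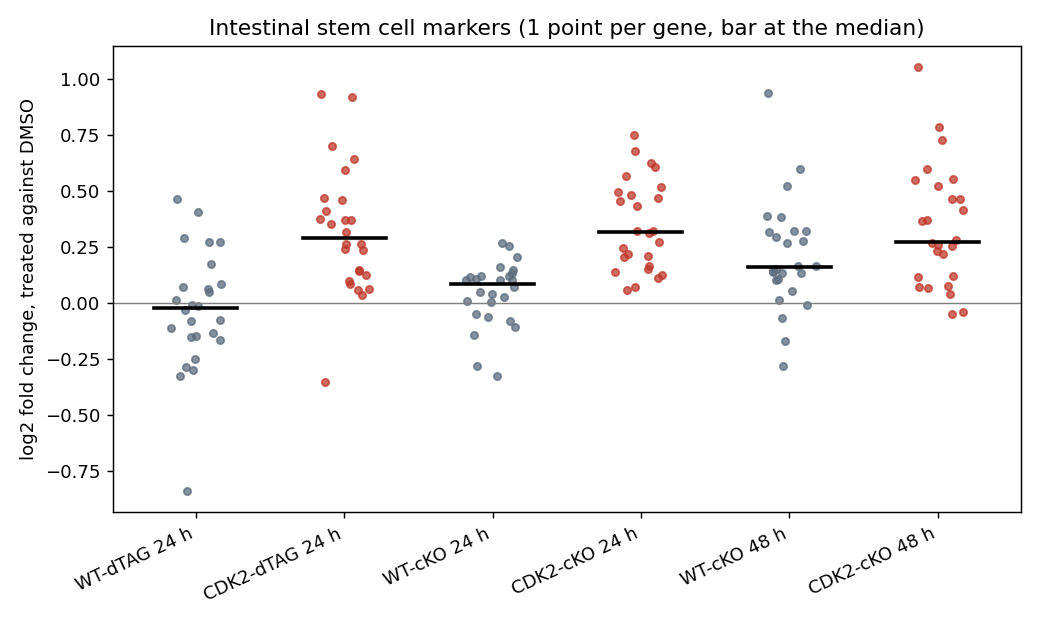
Log2 fold change of 26 intestinal stem cell markers, treated against DMSO, in the authors' deposited table; each point is a gene and each bar the median. CDK2-dTAG at 24 h and CDK2-cKO at 24 h had medians of 0.29 and 0.32, beside -0.02 and 0.09 in the matching wild types; at 48 h the medians were 0.28 in CDK2-cKO and 0.16 in WT-cKO.

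In CDK5-dTAG organoids 3 gene groups were higher after 6 h of dTAG-13 and 1 other group after 24 h, each by a small amount. At 6 h genes tied to CDK5 and neuronal-type substrates had a median of 0.25 with 16 of 20 positive (adjusted p = 0.00596; adjusted p = 0.0147 with an estimated correlation). The authors' deposited table gave 0.88 for the filament protein Vim, 1.15 for the tau gene Mapt, 1.37 for the syntaxin Stx1a and 1.35 for Cdk5r1, which encodes the CDK5 activator p35. Unfolded protein and integrated stress response genes rose by a median of 0.12, 29 of 33 positive (adjusted p = 4.49e-04); adjusted p = 0.959 with an estimated correlation. Of these, the endoplasmic reticulum chaperone genes Creld2, Hyou1 and Hspa5 stood at 0.63, 0.29 and 0.21 in the authors' deposited table. Immediate early genes rose by a median of 0.15, 21 of 26 positive (adjusted p = 0.0371); adjusted p = 0.959 with an estimated correlation. Here Myc was listed at 0.57 and Nr4a1 at 1.72 in the authors' deposited table. At 24 h the mitochondrially encoded genes rose by 0.18, 15 of 15 positive (adjusted p = 0.00339); adjusted p = 0.977 with an estimated correlation. The authors' deposited table gave mt-Nd3 0.59 and mt-Rnr2 0.36.

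The single genes and the wild-type comparison set limits on these shifts. In CDK5-dTAG organoids the authors' deposited table held 0 genes with FDR p under 0.05 at 6 h and 0 at 24 h, with 237 and 495 at unadjusted p under 0.05. The difference from WT-dTAG gave 0 genes at both times, with 263 at 6 h and 511 at 24 h at unadjusted p under 0.05. The CDK5-associated list differed from wild type by 0.18 at 6 h (adjusted p = 0.207), and its call in CDK5-dTAG ended on the genes with a median standard error of at most 0.5 (adjusted p = 0.134), as did that of the immediate early genes (adjusted p = 0.0650). Cytosolic ribosomal proteins differed from wild type by -0.15 at 6 h (adjusted p = 0.00428) and by -0.22 at 24 h (adjusted p = 2.30e-04), all 44 negative at both times. With an estimated correlation their adjusted p = 0.980 at 6 h and adjusted p = 0.983 at 24 h. Adjusted over the list alone, 0 members of the lists named for CDK5-dTAG passed.

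WT-cKO organoids are the wild type set beside CDK2-cKO on 4-OHT. The sample titles do not say whether they carry a tamoxifen-dependent Cre. A difference from CDK2-cKO can therefore not be assigned to CDK2 alone. After 24 h, 16 genes rose and 0 fell at FDR p under 0.05 in the authors' deposited table. The 5 with the largest rise were Smcp (log2 fold change 6.95, FDR p = 0.00405), Ccdc136 (6.45, FDR p = 0.00329), Akap12 (5.75, FDR p = 0.0149), Tnp1 (5.53, FDR p = 0.00329) and Gsg1 (5.49, FDR p = 0.0264) in the authors' deposited table. Smcp encodes a protein of the sperm mitochondrial capsule and Tnp1 (GRCm38 chromosome 1, 73015074 to 73015909) a transition protein of spermatid chromatin. Passed over among the 16 were 2 predicted genes without a symbol. With a Bonferroni adjustment 6 genes passed, and on the well measured genes alone 1 gene passed. Of the 16, 10 belong to a list of 69 spermatid and sperm transcripts written after these calls were seen. Over the 66 of them with values the median was 4.88, with 64 positive; no test is given on this list, which holds genes picked for their rise. The 55 listed genes neither called nor looked at before had a median of 4.67, with 53 positive (p = 4.57e-59; p = 2.10e-09 with an estimated correlation, cameraPR). They were listed because related genes were called in this same comparison, and they can rise together in a single library. These p-values are therefore no independent test. In this comparison 741 genes had unadjusted p under 0.05, and 644 of them were higher. Enterocyte markers fell at the same time by a median of -0.18, 32 of 38 negative (adjusted p = 0.0134); adjusted p = 0.939 with an estimated correlation. The authors' deposited table gave -0.85 for Adh6a and -0.75 for Xpnpep2. Estrogen-responsive genes had a median of -0.01 at 24 h (adjusted p = 0.818) and 0.06 at 48 h (adjusted p = 0.698).

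**Figure D3:**
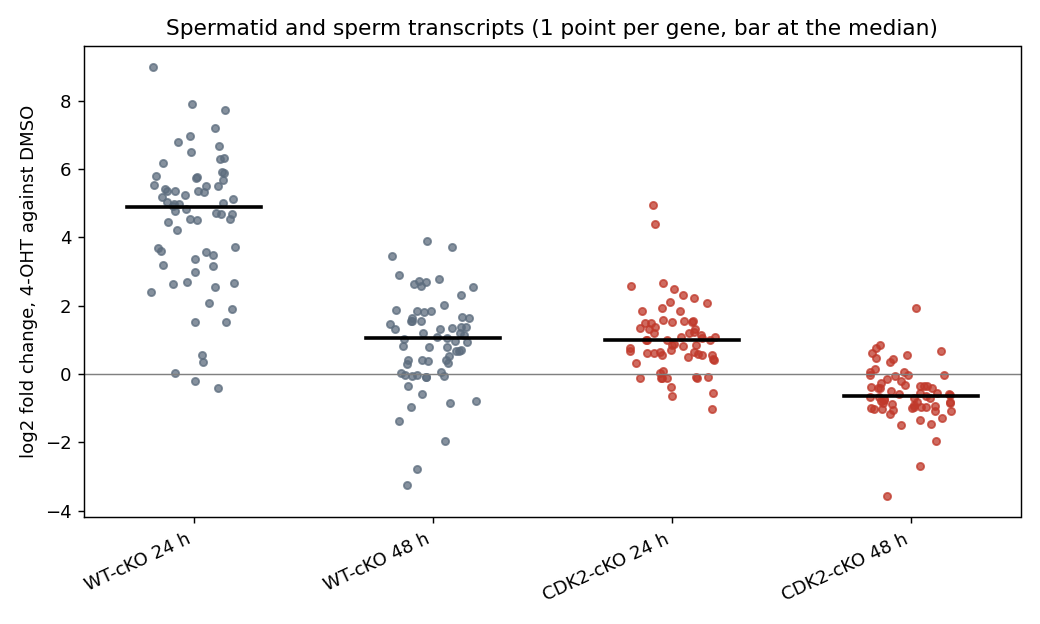
Log2 fold change of 66 spermatid and sperm transcripts, 4-OHT against DMSO, in the authors' deposited table; each point is a gene and each bar the median. The median was 4.88 in WT-cKO organoids at 24 h, 1.04 in WT-cKO at 48 h, 0.98 in CDK2-cKO at 24 h and -0.64 in CDK2-cKO at 48 h.

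In WT-cKO organoids markers of absorptive cells were lower after 48 h of 4-OHT than after 48 h of DMSO. Enterocyte markers had a median of -0.47, 35 of 38 negative (adjusted p = 1.97e-14; adjusted p = 0.0319 with an estimated correlation). The authors' deposited table gave -1.29 for the glucose transporter Slc2a2, -1.50 for Reg1, -0.90 for the intestinal alkaline phosphatase Alpi and -0.89 for sucrase-isomaltase, Sis. Xenobiotic genes controlled by AhR, PXR and CAR fell by -0.46, 18 of 20 negative (adjusted p = 4.30e-10; adjusted p = 0.0319 with an estimated correlation), and 3 of them passed when adjusted over the list alone. The cytochrome P450 genes Cyp2c66, Cyp2c55 and Cyp2b10 stood at -0.82, -0.52 and -1.23 in the authors' deposited table. Fatty acid oxidation and PPAR targets fell by -0.17, 16 of 22 negative (adjusted p = 0.00601; adjusted p = 0.0400 with an estimated correlation). Vnn1 was at -1.57 and Ehhadh at -1.44 in the authors' deposited table. Goblet cell markers rose by 0.23, 20 of 25 positive (adjusted p = 9.06e-05; adjusted p = 0.0319 with an estimated correlation), with Tpsg1 at 0.60 and Tff3 at 0.43 in the authors' deposited table. The same 48 h DMSO group was also compared with 24 h of DMSO, and there several lists moved the other way: enterocyte markers by 0.32, xenobiotic genes by 0.23, hypoxia and glycolysis genes by 0.21, stress response genes by 0.08, the DNA replication machinery by -0.15 and E2F and G1/S genes by -0.09. These shifts passed with the preset correlation and none held with an estimated correlation (adjusted p = 0.691, and adjusted p = 0.702 for the stress response). Goblet cell markers had a median of 0.00 there and enteroendocrine markers 0.19. For the lists that moved the other way, this comparison alone does not separate an effect of 4-OHT from the state of that DMSO group.

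A further 10 lists passed in WT-cKO organoids at 48 h with the preset correlation alone. Higher were the DNA replication machinery (0.19, adjusted p = 0.114 with an estimated correlation), E2F and G1/S genes (0.09, adjusted p = 0.262 with an estimated correlation), stem cell markers (0.16, adjusted p = 0.421 with an estimated correlation), enteroendocrine markers (0.31, adjusted p = 0.283 with an estimated correlation), Wnt targets (0.25, adjusted p = 0.492 with an estimated correlation) and ribosome biogenesis and MYC targets (0.07, adjusted p = 0.634 with an estimated correlation). Lower were NRF2 and glutathione genes (-0.24, adjusted p = 0.0943 with an estimated correlation), hypoxia and glycolysis genes (-0.20, adjusted p = 0.421 with an estimated correlation), unfolded protein and integrated stress response genes (-0.12, adjusted p = 0.377 with an estimated correlation) and cholesterol biosynthesis genes (-0.11, adjusted p = 0.421 with an estimated correlation). Cdc6, which loads replication helicases, stood at 0.81 and Cdc45 at 0.69 in the authors' deposited table, and the glutathione transferase Gstm3 at -0.85. Within the stress response list 1 gene passed when adjusted over the list alone. Over all genes the authors' deposited table held 0 with FDR p under 0.05 at 48 h and 455 at unadjusted p under 0.05. On the genes with a median standard error of at most 0.5, both the fatty acid and the cholesterol list had adjusted p = 0.0769.

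CDK2 knockout asks what deletion of the kinase changes, read beside the wild type on 4-OHT. After 24 h, stem cell markers rose in CDK2-cKO organoids: 26 of 26 were positive, with a median of 0.32 (adjusted p = 4.95e-10); adjusted p = 0.209 with an estimated correlation. The authors' deposited table gave Sox9 0.57, the Ephrin receptor Ephb3 0.75, the hyaluronan receptor Cd44 0.50 and the Wnt feedback gene Axin2 0.61. Wnt target genes rose by 0.37, 17 of 17 positive (adjusted p = 2.52e-06); adjusted p = 0.163 with an estimated correlation. Among p53 target genes 28 of 37 were positive, with a median of 0.20 (adjusted p = 4.62e-04); adjusted p = 0.163 with an estimated correlation. Zmat3 stood at 0.69 and Bbc3, which encodes the pro-apoptotic protein PUMA, at 0.80 in the authors' deposited table. Enteroendocrine markers rose by 0.18 (adjusted p = 0.0299; adjusted p = 0.716 with an estimated correlation), with the endocrine lineage factors Fev at 1.21 and Neurog3 at 1.10 in the authors' deposited table. Cytosolic ribosomal proteins fell by -0.16, all 44 negative (adjusted p = 1.74e-05; adjusted p = 0.716 with an estimated correlation). NRF2 and glutathione genes fell by -0.11 (adjusted p = 0.0296; adjusted p = 0.716 with an estimated correlation) and stress response genes by -0.10 (adjusted p = 0.0496; adjusted p = 0.716 with an estimated correlation). Spermatid transcripts had a median of 0.98 in this comparison (adjusted p = 4.81e-08; adjusted p = 0.351 with an estimated correlation).

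Set against wild type, 4 of the lists fixed in advance differed at 24 h with the preset correlation. The response of CDK2-cKO minus that of WT-cKO was 0.28 for stem cell markers, 23 of 26 positive (adjusted p = 9.17e-04), 0.35 for Wnt targets, 17 of 17 positive (adjusted p = 0.00487), 0.19 for p53 targets, 29 of 37 positive (adjusted p = 0.0117), and -0.14 for ribosomal proteins, 43 of 44 negative (adjusted p = 0.0117). With an estimated correlation each of these 4 had adjusted p = 0.990. The WT-cKO response subtracted here also holds the rise of testis transcripts: the 55 spermatid transcripts neither called nor looked at before differed by -3.38 (p = 3.01e-05 with an estimated correlation) and meiotic germ cell transcripts by -2.22 (adjusted p = 7.01e-04 with an estimated correlation). Both lists were written after the calls in WT-cKO organoids at 24 h were seen, so these p-values are no independent test. No single gene passed: the authors' deposited table held 0 with FDR p under 0.05 in CDK2-cKO organoids at 24 h and 324 at unadjusted p under 0.05, and the difference from wild type gave 0 and 443. In CDK2-cKO organoids at 24 h, 0 members of these lists passed when adjusted over the list alone. On the genes with a median standard error of at most 0.5 the NRF2 and stress response lists had adjusted p = 0.0705, and the enteroendocrine list did not pass either.

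At 48 h single genes changed in CDK2-cKO organoids: 1 rose and 5 fell at FDR p under 0.05 in the authors' deposited table. The comparisons used here hold none between DMSO times in CDK2-cKO organoids. For genes and lists alike, an effect of 4-OHT there cannot be told apart from the state of the DMSO group. Erfe, the hormone erythroferrone (GRCm38 chromosome 1, 91366430 to 91374217), rose by a log2 fold change of 3.92 (15.1-fold, FDR p = 0.00358) in the authors' deposited table. The standard error implied for Erfe was 0.76. Trib3, a stress-induced pseudokinase (chromosome 2, 152337422 to 152344032), stood at -1.27 (FDR p = 1.79e-04) and Ddit3, the stress transcription factor CHOP, at -1.45 (FDR p = 0.00358) in the authors' deposited table. Maoa, monoamine oxidase A (chromosome X, 16619698 to 16687818), was listed at -0.91 (FDR p = 0.0408), and the non-coding Snhg12 (chromosome 4, 132308623 to 132311024) at -1.08 (FDR p = 0.0408) in the authors' deposited table. Steap1 (chromosome 5, 5736317 to 5749326) was listed at -1.08 (FDR p = 0.0420) in the authors' deposited table. In WT-cKO organoids at 48 h the authors' deposited table gave Erfe 0.86, Trib3 -0.59, Ddit3 -1.04, Maoa -0.59, Snhg12 -0.18 and Steap1 -0.35. The genotypes differed by 3.05 for Erfe (95% interval 1.18 to 4.93), by -0.68 for Trib3 (-1.29 to -0.07), by -0.41 for Ddit3 (-1.21 to 0.39), by -0.32 for Maoa (-0.88 to 0.25), by -0.90 for Snhg12 (-1.57 to -0.23) and by -0.72 for Steap1 (-1.39 to -0.05). Over all genes each of these differences had adjusted p = 1.00.

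Gene groups moved as well in CDK2-cKO organoids at 48 h, where 15 of 30 lists passed with the preset correlation and 0 with an estimated correlation. Unfolded protein and integrated stress response genes fell by a median of -0.23, 30 of 33 negative (adjusted p = 1.38e-11); adjusted p = 0.132 with an estimated correlation. On this list 2 genes passed over all genes and 5 when adjusted over the list alone, and the authors' deposited table gave Atf5 -0.75 and Atf4 -0.49. Hypoxia and glycolysis genes such as Ndrg1 (-0.69) and Ldha (-0.39) in the authors' deposited table fell by -0.32, 27 of 28 negative (adjusted p = 5.58e-10; adjusted p = 0.203 with an estimated correlation). Xenobiotic genes fell by -0.45, 19 of 20 negative (adjusted p = 3.91e-08; adjusted p = 0.132 with an estimated correlation), and enterocyte markers by -0.39, 30 of 38 negative (adjusted p = 9.08e-07; adjusted p = 0.228 with an estimated correlation). The authors' deposited table gave Cyp2c66 -0.63, Reg1 -1.68, the lipid-loading protein Mttp -0.51 and Sis -0.82. Stem cell markers rose by 0.28, 24 of 26 positive (adjusted p = 1.33e-07; adjusted p = 0.203 with an estimated correlation), and Wnt targets by 0.39, 15 of 17 positive (adjusted p = 9.79e-06; adjusted p = 0.147 with an estimated correlation). Sox9 was listed at 0.47, Rgmb at 0.79, Myc at 0.80 and Ccnd1 at 0.58 in the authors' deposited table.

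Replication genes rose with them. The DNA replication machinery had a median of 0.28, 29 of 36 positive (adjusted p = 5.12e-07; adjusted p = 0.132 with an estimated correlation), and E2F and G1/S genes 0.17, 26 of 35 positive (adjusted p = 9.89e-05; adjusted p = 0.203 with an estimated correlation). The authors' deposited table gave the helicase subunit Mcm2 0.41, the flap endonuclease Fen1 0.43, Orc1 0.88 and E2f7 1.02. Markers of secretory cells were higher: enteroendocrine 0.43 (adjusted p = 1.93e-06; adjusted p = 0.132 with an estimated correlation), goblet 0.15 (adjusted p = 0.0195; adjusted p = 0.228 with an estimated correlation) and Paneth 0.29 (adjusted p = 0.0322; adjusted p = 0.361 with an estimated correlation). Insm1 stood at 0.80 and the proglucagon gene Gcg at 0.62 in the authors' deposited table, while Pax6, also on the enteroendocrine list, stood at -1.81. The p53 targets rose by 0.16 with 21 of 37 positive (adjusted p = 0.0130; adjusted p = 0.228 with an estimated correlation). NRF2 and glutathione genes fell by -0.16 (adjusted p = 2.53e-04; adjusted p = 0.228 with an estimated correlation), cholesterol biosynthesis genes by -0.09 (adjusted p = 0.0228; adjusted p = 0.228 with an estimated correlation) and ribosomal proteins by -0.10 (adjusted p = 0.0416; adjusted p = 0.669 with an estimated correlation). The 15 lists that did not pass included Notch pathway genes (median 0.30, adjusted p = 0.0579), NF-kB and inflammatory genes (-0.11, adjusted p = 0.251), apoptosis and cell death genes (0.02, adjusted p = 0.402), heat shock genes (0.05, adjusted p = 0.528), gastric and pancreatic markers (-0.12, adjusted p = 0.159), and fatty acid oxidation and PPAR targets (-0.08, adjusted p = 0.309) and ribosome biogenesis and MYC targets (0.06, adjusted p = 0.125), which had both passed in WT-cKO organoids at 48 h.

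Of the 15 lists that passed, all but the p53, Paneth and ribosomal lists also passed, in the same direction, in WT-cKO organoids at 48 h. Of the lists fixed in advance, only the p53 targets differed at 48 h between CDK2-cKO and WT-cKO organoids with the preset correlation, by a median of 0.31 with 24 of 37 positive (adjusted p = 7.25e-04); adjusted p = 0.242 with an estimated correlation. Spermatid transcripts differed by -1.67, 11 of 66 positive (adjusted p = 2.34e-09; adjusted p = 0.607 with an estimated correlation). Bbc3 was listed at 0.46 in CDK2-cKO and -1.04 in WT-cKO organoids in the authors' deposited table, and their difference (95% interval 0.41 to 2.59) had adjusted p = 1.00 over all genes. Differences that did not pass were -0.10 for the stress response list (adjusted p = 0.0577), 0.17 for enterocyte markers (adjusted p = 0.146) and 0.06 for stem cell markers (adjusted p = 0.293). Over all genes the difference between genotypes gave 0 genes, with 317 at unadjusted p under 0.05. The authors' deposited table held 550 genes at unadjusted p under 0.05 in CDK2-cKO organoids at 48 h.

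**Figure D4:**
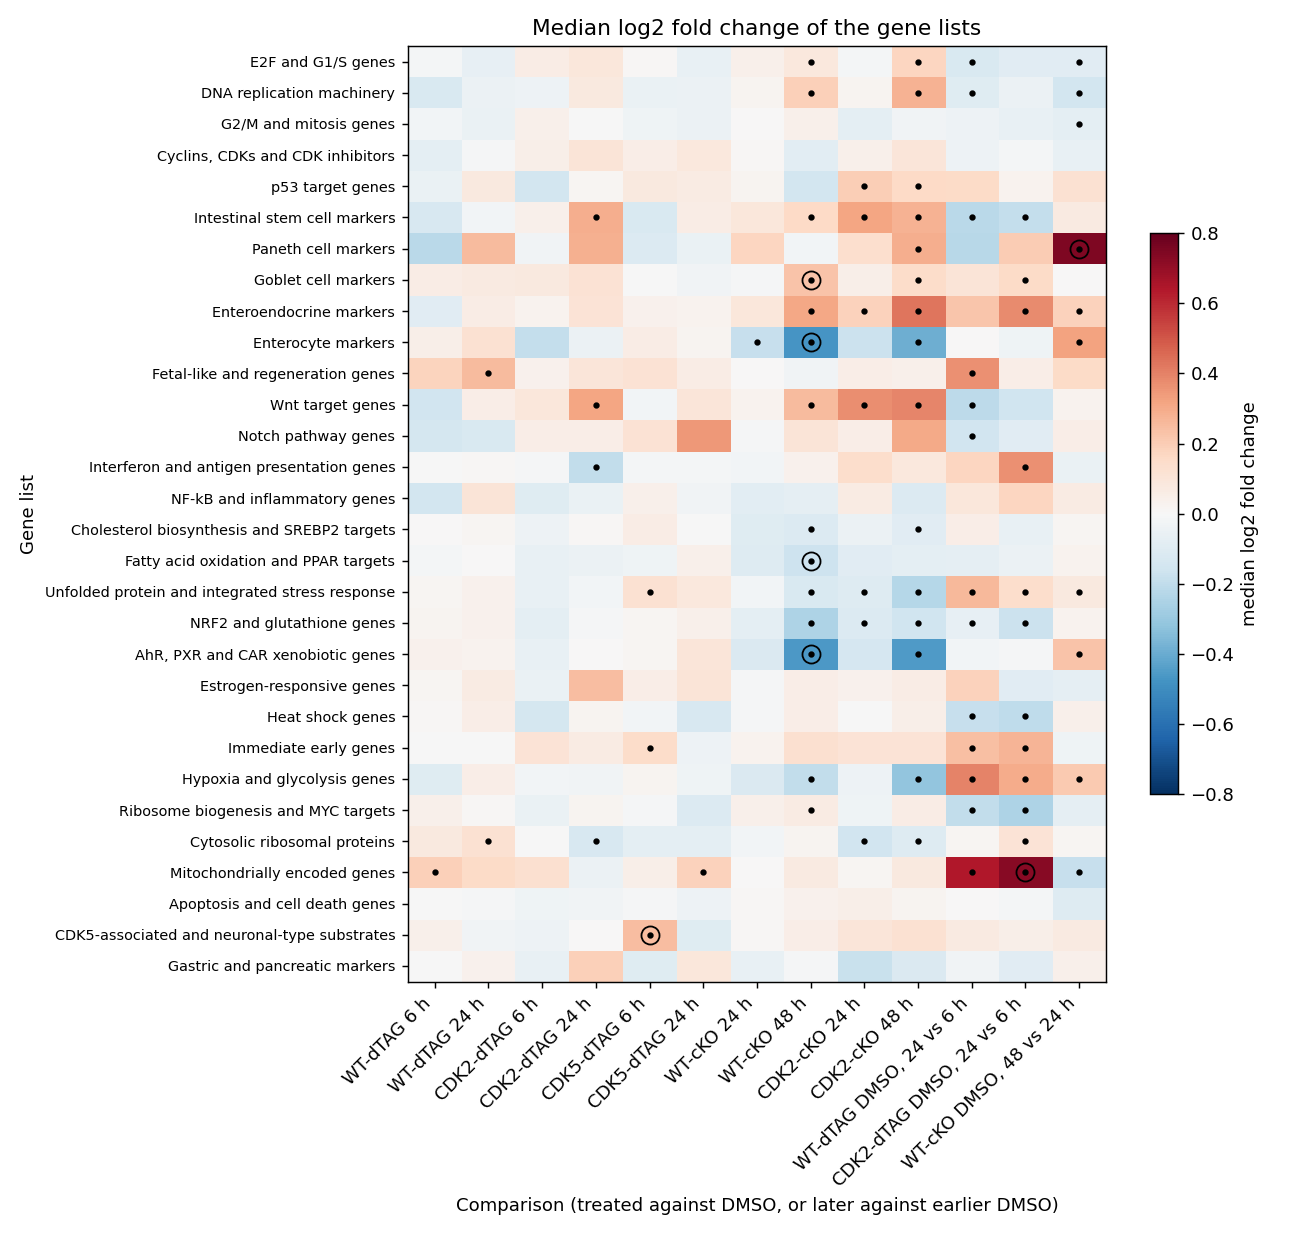
Median log2 fold change of 30 gene lists (vertical axis) in the 13 comparisons (horizontal axis), from -0.8 (blue) to 0.8 (red). A dot marks adjusted p under 0.05 with the preset correlation and a ring the calls that also hold with an estimated correlation, such as enterocyte markers (-0.47) in WT-cKO organoids at 48 h.

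Over the 10 treatment comparisons 48 list calls passed with the preset correlation and 5 of them with an estimated correlation. The 5 were the CDK5-associated list in CDK5-dTAG at 6 h and, in WT-cKO at 48 h, the enterocyte, xenobiotic, goblet and fatty acid oxidation lists. The estimate counts movement of a list in other comparisons as correlation. Holding with it therefore does not rank these 5 above lists that moved in several comparisons.

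The last comparison asks whether degradation and deletion of CDK2 shift the same genes. Across all 24905 genes the response to 24 h of CDK2 degradation correlated with that to 24 h of CDK2 knockout at Spearman rho 0.0904 and Pearson r 0.00884. With 48 h of knockout the values were rho 0.0633 and r 0.00380. Genes are not independent replicates, so no p-value is attached. In the 9526 genes with a median standard error of at most 0.5 the correlation was higher, at rho 0.291 and r 0.223 for 24 h and rho 0.168 and r 0.154 for 48 h. These ranked 1 and 2 by Spearman rho among the 24 pairs that set a degron comparison against a knockout comparison. Rank 3 was CDK2-dTAG at 24 h against WT-cKO at 48 h (rho 0.116), and rank 6 CDK2-dTAG at 24 h against WT-cKO at 24 h (rho 0.0596). The ranking is therefore not particular to pairs in which both genotypes target CDK2. After subtraction of the wild-type responses rho was 0.0304 for 24 h and 0.0167 for 48 h over all genes, and 0.166 and 0.0744 in the 9526 genes. Both treatments showed higher stem cell markers and Wnt targets and lower ribosomal proteins at 24 h with the preset correlation, and none of these 6 list calls held with an estimated correlation. With 0 genes called after degradation, an overlap of called genes could not be tested.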

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

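In the correlation pattern weighed here, the test against the wild-type responses of both arms was chosen only after the result was seen.

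These results stood out because the response of a gene list differed between a genotype and its wild type by a test of the difference itself with the preset correlation; none of the 9 held with an estimated correlation. In CDK2-dTAG organoids at 24 h the median difference was 0.32 for stem cell markers and -0.26 for cytosolic ribosomal proteins (adjusted p = 0.918 with an estimated correlation for both). Ribosomal proteins differed in CDK5-dTAG organoids by -0.15 at 6 h and -0.22 at 24 h (adjusted p = 0.980 and adjusted p = 0.983 with an estimated correlation). Both genotypes are set against the same WT-dTAG responses, in which ribosomal proteins had a median of 0.08 at 6 h and 0.12 at 24 h. In CDK2-cKO organoids at 24 h the median difference was 0.28 for stem cell markers, 0.35 for Wnt targets, 0.19 for p53 targets and -0.14 for ribosomal proteins (adjusted p = 0.990 with an estimated correlation for each), set against a WT-cKO response that also holds the spermatid transcripts. At 48 h p53 targets differed by 0.31 in CDK2-cKO organoids (adjusted p = 0.242 with an estimated correlation).

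Across well measured genes, the responses to CDK2 degradation and CDK2 knockout correlated at 24 h with r = 0.223 (bootstrap SD over genes 0.0137), the highest of 24 pairs across the arms. Given both wild-type DMSO time comparisons the partial r was 0.203, so their linear part accounted for little of the correlation. This does not decide on a shared shift along culture time. The wild-type comparisons hold no DMSO group of CDK2-dTAG or CDK2-cKO organoids, so the state of those groups was not removed. Across the same genes the CDK2-cKO response at 24 h had r = -0.168 with the WT-dTAG DMSO time comparison. The wild-type responses of both arms at 24 h had r = -0.0343. Their z scores had a spread of only 0.719 and 0.694, so a low r can come from weak responses alone. This r therefore does not decide on a response that wild type shares. The CDK2-dTAG response at 24 h had r = 0.0928 with WT-cKO at 48 h and r = -0.0626 with WT-dTAG at 24 h. A trend with GC content of the last 500 transcript bases, transcript length or precision cannot be told apart: the r of residuals was 0.129, between the bounds set for it, while the stem cell medians moved from 0.29 to 0.25 in CDK2-dTAG and from 0.32 to 0.28 in CDK2-cKO. With the wild-type response subtracted on both sides r was 0.119. Loss of CDK2 itself remains open as a hypothesis, and no single gene passed in either comparison.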

How the results depend on the processing

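Of the tests reported here, the estimated correlation, the fold change limit for treatments and differences, the subtraction of wild type in the agreement and the genes called in either comparison were planned; all others were chosen after the table was seen.

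No paired analysis was possible because the table holds comparisons, not samples; for the same reason leaving out replicates, other splits of the samples, other normalizations, filters and pseudocounts, another count tool, fits on only the named groups and a test of lists by rotation were not run. Depth per sample is unknown, so precision rests on the derived standard errors. For knockout at 24 h no gene was called in either comparison, so that agreement has no value.

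A fold change limit of 1.5 moved no count of genes by more than 1.5 times. By its stricter construction the Bonferroni adjustment left 9 genes in WT-dTAG and 5 in CDK2-dTAG organoids between DMSO times, 6 in WT-cKO at 24 h and 3 in CDK2-cKO at 48 h. On well measured genes alone, with fewer genes tested, 34 genes passed between DMSO times in WT-dTAG and 1 in WT-cKO organoids at 24 h. Centring z and rescaling it by its own spread, which was below 1 in every comparison, with adjustment over the well measured genes, raised these counts: WT-dTAG 10 at 6 h and 7 at 24 h, CDK2-dTAG 10 and 1, CDK5-dTAG 8 and 16, WT-cKO 3 and CDK2-cKO 11 at 48 h, and between DMSO times 40 in WT-dTAG, 19 in CDK2-dTAG and 1 in WT-cKO. For differences from wild type it gave 16 in CDK2-dTAG at 6 h, 2 and 1 in CDK5-dTAG at 6 and 24 h, and 8 in CDK2-cKO at 48 h.

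Spearman rho between CDK2 degradation and knockout was 0.0304 for 24 h and 0.0167 for 48 h after subtraction of wild type, 0.291 and 0.168 in well measured genes, and 0.6 over the 6 genes called in either comparison at 48 h; the cause was not tested. The 48 list calls in treatment comparisons became 5 with an estimated correlation. By construction this estimate rises where a list moves in other comparisons, so a list that moves in several can fail for that reason. How far this accounts for the drop was not tested. Over all comparisons and differences the estimated correlation kept 7 list calls and ended 85, ranks kept 88 and ended 4, all genes kept 90 and ended 2, and well measured genes kept 77 and ended 15; none reversed.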

Other observations

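The DMSO time comparisons, the testis lists, the list tests on 55 spermatid genes, and the tests of a shared 4-OHT response and of a missing library were chosen only after results were seen, as were the single genes named here.

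Between 6 and 24 h of DMSO WT-dTAG and CDK2-dTAG organoids changed more than with dTAG-13, after which 0 genes were called in either. The authors' deposited table held 19 genes higher and 1 lower at FDR p under 0.05 in WT-dTAG organoids, and 8 higher and 1 lower in CDK2-dTAG organoids. Mitochondrially encoded genes rose by a median of 0.64 in WT-dTAG (adjusted p = 1.02e-22; adjusted p = 0.0554 with an estimated correlation) and 0.73 in CDK2-dTAG organoids (adjusted p = 2.88e-35; adjusted p = 0.00172 with an estimated correlation), with 15 of 15 positive in both. The authors' deposited table gave mt-Co1 1.24 and 1.40, and the growth factor Areg 1.96 and 2.03. For Fkbp5, a glucocorticoid-induced chaperone, it was -1.56 in WT-dTAG and -1.75 in CDK2-dTAG organoids in the authors' deposited table. Stress response genes rose by 0.26 in WT-dTAG (adjusted p = 3.33e-08; adjusted p = 0.212 with an estimated correlation) and 0.14 in CDK2-dTAG organoids (adjusted p = 4.04e-05; adjusted p = 0.441 with an estimated correlation). The authors' deposited table gave Trib3 1.64 and 1.02, Ddit3 1.63 and 1.21, and Atf3 1.69 and 1.83. Hypoxia and glycolysis genes rose by 0.40 and 0.30 (adjusted p = 0.212 and adjusted p = 0.441 with an estimated correlation). Ribosome biogenesis genes had medians of -0.19 and -0.25 (adjusted p = 0.371 and adjusted p = 0.244 with an estimated correlation), and heat shock genes of -0.18 and -0.20 (adjusted p = 0.212 and adjusted p = 0.441 with an estimated correlation). Stem cell markers had medians of -0.21 and -0.19 (adjusted p = 0.409 and adjusted p = 0.744 with an estimated correlation). Across well measured genes these changes correlated between the genotypes with r = 0.464.

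From 24 to 48 h of DMSO in WT-cKO organoids, Paneth cell markers rose by a median of 0.75, 12 of 13 positive (adjusted p = 1.38e-07; adjusted p = 0.00612 with an estimated correlation). The authors' deposited table gave the protease Mmp7 1.23, the defensin Defa26 1.65 and the antimicrobial Ang4 0.84. The authors' deposited table held 0 genes with FDR p under 0.05 there and 354 at unadjusted p under 0.05. Enterocyte markers rose by 0.32 (adjusted p = 9.61e-06; adjusted p = 0.691 with an estimated correlation) and G2/M and mitosis genes had a median of -0.08 (adjusted p = 0.00537; adjusted p = 0.691 with an estimated correlation). The 48 h DMSO group here is also the reference for 48 h of 4-OHT. The tuft, fibroblast, immune, and endothelial and neural lists had 4, 1, 1 and 2 members measured well enough and were not tested. Among them the authors' deposited table gave Adh1 -0.86 in WT-cKO at 48 h (and a lower value still in CDK2-cKO, p = 0.00556), Vim 0.88 in CDK5-dTAG at 6 h, Csf1r 1.72 in WT-dTAG at 24 h and Pecam1 1.15 in CDK5-dTAG at 24 h, none past FDR p under 0.05.

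Spermatid transcripts were higher in WT-cKO organoids after 24 h of 4-OHT, with Prm1 at 5.36 and Tnp2 at 5.36 in the authors' deposited table. A candidate source is RNA or reads from testis in the 4-OHT libraries: the 55 listed genes neither called nor looked at before had a median of 4.67, 53 of them positive, and meiotic germ cell transcripts 3.91. Sertoli and Leydig cell transcripts were higher too, by a smaller median of 0.81 with 11 of 17 positive (cameraPR adjusted p = 0.00327, and adjusted p = 0.00154 with an estimated correlation). A response to 4-OHT shared equally by both genotypes would leave no difference between them. The WT-cKO response exceeded that of CDK2-cKO by a median of 3.58, with 64 of 66 positive. Over the 55 genes neither called nor looked at before it did so by 3.38, with 53 positive (p = 3.01e-05 with an estimated correlation, cameraPR). The list was chosen for its rise in WT-cKO, and its genes can move together in a single library, so these values do not settle the question. A response of wild type alone stays open, untested, as does which library holds the signal; 0 of the listed genes are on a fixed list, and 5 have a median standard error of at most 1. Smaller medians of both signs occurred elsewhere: 0.98 in CDK2-cKO at 24 h (adjusted p = 4.81e-08; adjusted p = 0.351 with an estimated correlation), 1.04 in WT-cKO (adjusted p = 1.04e-05; adjusted p = 0.661) and -0.64 in CDK2-cKO (adjusted p = 0.00470; adjusted p = 0.748) at 48 h, and -1.23 in WT-dTAG at 24 h (adjusted p = 5.91e-08; adjusted p = 0.361), so a weaker testis signal in other groups is not excluded.

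Standard errors were larger where the CDK2-dTAG 6 h DMSO group entered: relative to WT-dTAG at 6 h the median ratio over 325 best measured genes was 1.12 in both comparisons with this group and 1.00 to 1.01 in the others. The ratio for 2 libraries against 3 is 1.12, and both values lay within 0.000548 of it, so 1 of the 3 labelled libraries may not have entered the fit. A shallower library is argued against, because the ratio differed between less well and best measured genes by 0.00453 at most. No biological explanation was tested.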
